A study of Mus musculus with 12 samples.

How the data were processed

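The series measured RNA in the striatum of male C57BL/6J mice at postnatal day 70, in synaptosomal input RNA and in RNA from synaptosomal polyribosomes, from wild-type (WT) mice and mice with a Shank3 transgene (TG). Each of the 4 groups had 3 libraries. Per the labels' protocols, libraries were made with a stranded total RNA kit, which does not select polyadenylated RNA. Per the submitters' processing notes, the tools were Salmon 1.1.0, R 3.6.2 and DESeq2 1.26.0 with the build GRCm38. The annotation, the summary from transcripts to genes and the model behind the normalization are not given in the sources used here. Nor is it stated that input and polysome libraries were quantified with the same index and settings, which bears on every value of polysome against input.

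A single table of 21492 genes and 12 columns was deposited, and its signal is the authors' normalized estimated count per gene, although the table is named for counts. The values are not whole numbers. Low values bunched near multiples of a step, read as the value of 1 read, but only 33.4% to 45.8% of the values up to 20 reads lay within 0.1 read of a whole number. Reads per gene could therefore not be recovered, and no test of counts was run. The step gave an estimated depth of 62.3 to 85.3 M reads per input library and 76.3 to 101.7 M reads per polysome library. A read was worth 1.27 to 1.81 in input and 0.616 to 0.847 in polysome libraries, so a low gene was measured less precisely in input. Of the gene identifiers, 21465 matched GENCODE mouse release M21, which is on GRCm38 and gave symbols, coordinates, exonic length and the share of 31-base sequences that a gene has in common with other genes. No other column was present, and no pair of columns was identical (lowest and highest correlations 0.957 and 0.988).

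Each comparison was fitted with limma 3.58.1 in R 4.3.3 on log2(value + 1), with a trend of variance on mean level (eBayes). A gene was tested when at least 3 fitted libraries reached a value of 10. Fold changes are on the log2(value + 1) scale, which understates those of low genes, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. Genotype was compared within input and within polysome libraries, 6 each. The comparison of polysome with input, in WT and in TG, and the difference of the genotype effect between fractions (the interaction) came from 1 fit of all 12 libraries. The labels do not say that the samples of a group came from separate animals, so p-values measure the spread between these samples, which may in part be technical.

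The libraries share the numbers 1 to 3 across groups. Deviations from the group means correlated at 0.28 to 0.55 in the 12 pairs of same-numbered libraries, and at -0.41 to -0.04 between libraries of different numbers. Deviations cancel within a group, so the negative values largely follow from the positive ones and are not separate evidence of pairing. All 12 pairs were each other's best match, and the second principal component separated the numbers. The pairing comes from these values and from the shared numbers, since the labels do not say what a number stands for. The main fits had no block, and fits with a replicate block were run beside them. For genotype within input or polysome, the block was the number. For polysome against input and the interaction, it was the number within each genotype, which pairs the input and polysome libraries of that genotype.

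The 29 gene lists were fixed before the data were examined. They cover synaptic and translational genes, mitochondrial genes, markers of neuronal and other cell types, blood, nuclear long noncoding RNAs, immediate early genes, dendritic transcripts, the proteasome and secretory chaperones. Each was tested with camera at a preset correlation of 0.01 between genes, two-sided, adjusted over the lists of a comparison. An estimated correlation was the alternative. Lists needed at least 3 measured members.

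The genes named were chosen by a rule fixed at the same time. It takes Shank3, and the 10 largest rises and 10 largest falls among called genes with a mean log2 level of at least 5, without overlap of the groups and without predicted or pseudogene symbols. It takes from each list the called members with the largest rise and fall, or the member with the smallest p where none was called. Where fewer than 5 genes were called, the 5 with the smallest p are named as not passing. The rule was applied to all comparisons but polysome against input in TG.

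The alternatives were TMM scaling, other filters and pseudocounts, no variance trend, other sets of libraries in the fit, the replicate block, and each library left out in turn. Alternatives added after the data were examined left out genes sharing over 50% of their sequence, left out all libraries of a number in the block fit, removed the trend on exonic length, and used a threshold of 0.1. The fits were tested on simulated data in which 200 genes changed by known sizes. In input, run on 16341 genes, 14.9% of genes changed by 1 on the log2 scale and 60.6% of those changed by 2 were recovered. In polysome, run on 16312 genes, these shares were 22.4% and 80.3%. For the interaction, run on 16962 genes, they were 2.99% and 48.5%. With the replicate block they were 29.85% and 65.15% in input, 40.3% and 80.3% in polysome, and 10.45% and 60.61% for the interaction. A simulated list of 40 genes shifted by 0.5 was called by camera in every comparison, except with an estimated correlation in the block fit of input (adjusted p = 0.158) and polysome (0.154). A call lost in that setting therefore says little about lists with smaller medians. The simulated genes varied independently of each other, whereas markers of medium spiny neurons in input had an estimated correlation of 0.90. The simulation therefore does not show how well an estimated correlation recovers lists of correlated genes, with or without the block.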

Results

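Synaptosomes are nerve terminals with attached postsynaptic membrane that seal off when brain tissue is homogenized, and polyribosomes are transcripts loaded with several ribosomes. RNA of striatal synaptosomes (input) and of the polyribosomes isolated from them (polysome) was sequenced in WT and Shank3 TG mice, with 3 libraries in each of 4 groups. Estimated depth was 70.1 ± 13.1 M reads in WT input, 74.8 ± 9.62 in TG input, 94.1 ± 5.82 in WT polysome and 93.0 ± 14.5 in TG polysome (mean ± SD, n = 3). Mitochondrial ribosomal RNA took 43.7% ± 4.03 of the normalized signal in WT input and 42.2% ± 3.98 in TG input, against 30.7% ± 4.79 and 26.0% ± 2.56 in the polysome libraries (SD, n = 3). Nuclear protein-coding genes took 45.0% ± 4.82 of WT input and 64.2% ± 5.54 of WT polysome signal.

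**Figure D1:**
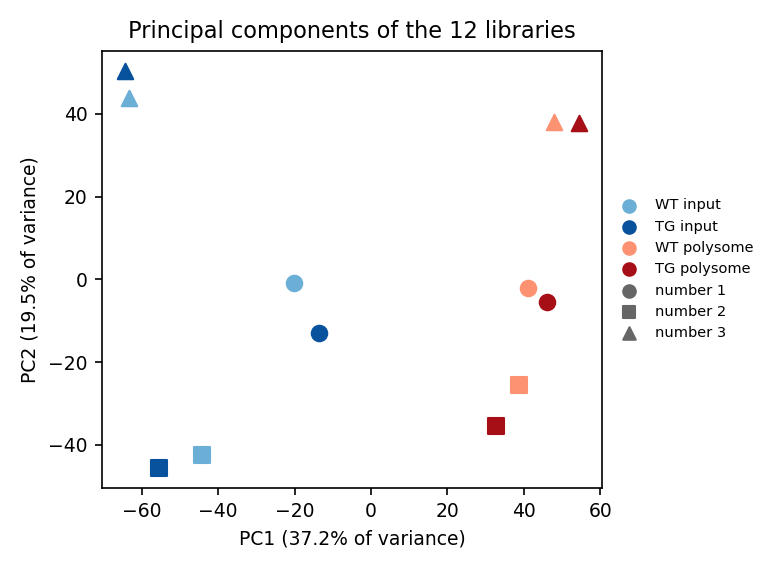
Principal components of log2(value + 1) of 16962 genes in the 12 libraries, with colour for the group and marker shape for the replicate number. PC1 (37.2% of the variance) separates polysome from input, and PC2 (19.5%) separates the replicate numbers.

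The first comparison asked which synaptosomal transcripts differ with the Shank3 transgene. Shank3, a scaffold protein gene of the excitatory postsynaptic density, had 12355 ± 6210 normalized counts in TG input and 4047 ± 1871 in WT input (mean ± SD, n = 3). It was 2.57, 4.20 and 2.41 times higher in the TG library of numbers 1, 2 and 3. The gene lies on chromosome 15 at 89499623 to 89560261 of GRCm38, and the log2 difference was 1.57 ± 0.49 (SE) with an adjusted p of 1.00 (limma). No gene of 16341 passed the test, and 80 had an unadjusted p under 0.05. The smallest p-values, none passing, belonged to Spink10 (log2 difference 1.48 ± 0.37), Baiap2l2 (1.36 ± 0.34), Tmem254a (-0.79 ± 0.21), Nfxl1 (-0.88 ± 0.24) and Rps6kb2 (-1.08 ± 0.29), which encodes an S6 kinase of the mTORC1 pathway. Tmem254a shares 73% of its sequence with other genes, so its value is uncertain.

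Several gene lists stood apart from other genes in TG input at the preset correlation, and all of these calls were lost with an estimated one. Markers of medium spiny neurons, the principal cells of the striatum, were higher in 21 of 21 members (median log2 difference 0.20, adjusted p = 0.00294, camera; adjusted p = 0.932 with an estimated correlation). Lrrc10b had the smallest p among them (0.46 ± 0.47). Immediate early genes, which respond to neuronal activity, were higher in 17 of 20 members (median 0.23, adjusted p = 1.5e-05, and adjusted p = 0.932 with an estimated correlation), with Fosl2 at 0.37 ± 0.18. The Shank family (4 of 4 higher, median 0.31, adjusted p = 0.0144), which contains Shank3 itself, and oligodendrocyte markers (16 of 19 higher, median 0.085, adjusted p = 0.0299) also lay higher, while markers of cortical excitatory neurons (15 of 16 lower, median -0.12, adjusted p = 0.0299) and secretory chaperones (20 of 23 lower, median -0.090, adjusted p = 0.0111) lay lower. The adjusted p of these 4 lists was 0.932 with an estimated correlation. The list called the Shank family here also held Shank1 (0.52 ± 0.79), Shank2 (0.11 ± 0.27) and Sharpin (0.055 ± 0.26). Sharpin encodes a protein that binds Shank proteins and is not a Shank gene itself. The pair of number 1 ran against the medians of the Shank family (-0.043) and immediate early genes (-0.091), and the pair of number 3 against those of medium spiny markers (-0.024), cortical markers (0.17) and secretory chaperones (0.11). Adjusted over the list alone, no member of any list passed without the block, and Shank3 and Shank1 passed with it. In input the medium spiny markers also differed between replicate numbers, with a median 1.06 higher in number 2 than in the others, and cortical markers differed the other way (-0.84). In the replicate block fit, 6 further lists passed at the preset correlation. Markers of indirect-pathway neurons (adjusted p = 0.000246), direct-pathway neurons (0.0178), FMRP-bound transcripts (0.00528), blood (0.00528) and dendritic transcripts (0.0223) lay higher and cytosolic ribosomal proteins (0.0206) lower, with adjusted p from 0.508 to 0.938 for these lists with an estimated correlation in that fit. The medians of ribosomal proteins in the 3 pairs were 0.13, -0.33 and 0.043, so their lower value rests on number 2, and number 1 ran against FMRP-bound transcripts (-0.15) and number 3 against dendritic transcripts (-0.017).

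**Figure D2:**
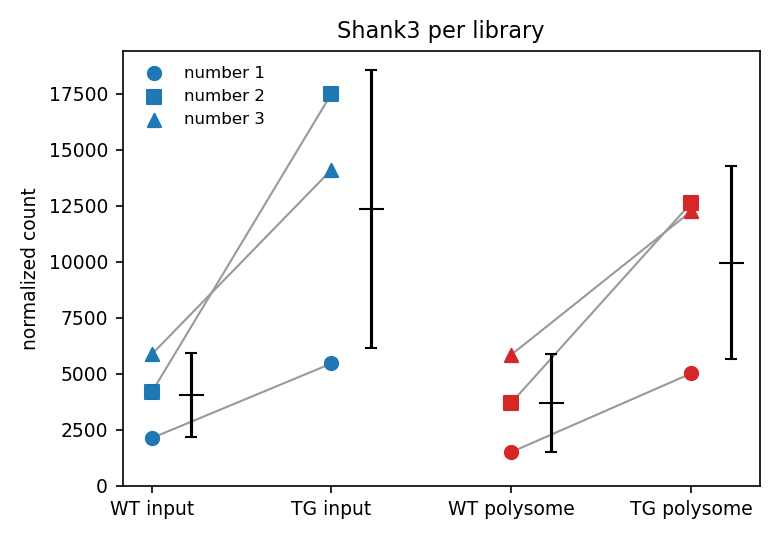
Shank3 normalized counts per library (points, marker shape by replicate number), with lines joining WT and TG libraries of the same number and bars for the group mean ± SD (n = 3). The TG library lies above the WT library of its number in all 3 pairs of both fractions, by 2.10 to 4.20 times.

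The second comparison asked which transcripts on synaptosomal polyribosomes differ with the transgene. Shank3 had 9964 ± 4292 normalized counts in TG polysome and 3684 ± 2174 in WT polysome libraries (mean ± SD, n = 3), and was 3.34, 3.41 and 2.10 times higher in TG in numbers 1, 2 and 3. Its log2 difference was 1.53 ± 0.52 (SE, adjusted p = 1.00, limma), and with the replicate block it passed the test (SE 0.15, adjusted p = 0.0205). No gene of 16312 passed without the block, with 53 at an unadjusted p under 0.05, and Shank3 was the 1 gene that passed with it. Without number 2 the blocked Shank3 difference of 1.40 did not pass (adjusted p = 0.603), and without number 3 the block called 89 genes. The smallest p-values without the block, none passing, were those of Enpp3 (-1.34 ± 0.32), Gm4117 (2.90 ± 0.73), Neb (-1.42 ± 0.37), Cyp4f15 (-0.57 ± 0.15) and Gm42418 (1.87 ± 0.51).

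Transcripts encoded by mitochondrial DNA were lower in TG polysome libraries in 12 of 13 members, with a median log2 difference of -0.49 (adjusted p = 5.3e-11, camera; adjusted p = 0.781 with an estimated correlation). Their median was lower in all 3 pairs, by log2 differences of -0.54, -0.21 and -0.73, and mt-Nd4 had the smallest p (-0.57 ± 0.25). Mitochondrial ribosomal RNA also took a lower share of the TG than of the WT polysome library in each pair (26.9% and 34.0%, 23.1% and 25.2%, 28.0% and 32.8%), so the mitochondrial RNA content of the preparations differed in the same direction. Immediate early genes (17 of 20 higher, median 0.15, adjusted p = 0.00490) and medium spiny neuron markers (20 of 21 higher, median 0.18, adjusted p = 0.0289) lay higher, and cortical excitatory markers lay lower (14 of 16, median -0.15, adjusted p = 0.00869). With an estimated correlation the adjusted p was 0.781 for the first and 0.909 for the other pair. Proteasome subunits (24 of 31, adjusted p = 0.00490), cytosolic ribosomal proteins (61 of 81, 0.0210), the Shank family (3 of 4, 0.0367) and hemoglobin and other blood genes (5 of 5, 0.0448) lay higher, and nuclear long noncoding RNAs (9 of 11, 0.0184) and choroid and ependymal markers (10 of 13, 0.0210) lower. For these 6 lists the adjusted p with an estimated correlation was 0.781 to 0.909. The medians of immediate early genes in the pairs of numbers 1, 2 and 3 were -0.043, -0.041 and 0.38, so their higher value rests on number 3, and those of choroid and ependymal markers were 0.011, -1.22 and 0.14, so their lower value rests on number 2. Number 3 ran against the Shank family (-0.18), cortical markers (0.075) and medium spiny markers (-0.010), and number 2 against ribosomal proteins (-0.16), the proteasome (-0.031) and nuclear long noncoding RNAs (0.19). Adjusted over the list alone, no member of any list passed without the block. With it 6 of the 13 mitochondrially encoded transcripts passed as lower (mt-Nd1, mt-Nd2, mt-Nd4, mt-Nd5, mt-Atp8 and mt-Cytb), as did the cortical marker Cux2 (-0.55), and Shank3 passed as higher in its lists. In the replicate block fit the direct-pathway (0.0201), indirect-pathway (0.00144) and oligodendrocyte (0.00560) markers passed as higher and presynaptic release genes (0.0207) as lower, with an adjusted p = 0.671 with an estimated correlation in that fit. Number 3 ran against the presynaptic genes (0.038) and number 2 against the direct-pathway markers (-0.0039).

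The interaction asked whether the genotype difference itself differs between polysome and input. It measures a change in polysome values relative to input values, and the share of a transcript on polyribosomes was not measured. For Shank3 the difference of log2 differences was -0.04 ± 0.80 (adjusted p = 1.00), with 0.38, -0.30 and -0.20 in numbers 1, 2 and 3, and from -0.59 to 0.39 with single libraries left out, so its sign is not settled. Mitochondrially encoded transcripts had a lower polysome-to-input ratio in TG than in WT in 12 of 13 members (median -0.51, adjusted p = 3.4e-05, camera; adjusted p = 1.00 with an estimated correlation). Their medians in numbers 1, 2 and 3 were -0.00073, -0.39 and -1.16, so number 1 hardly differed. In input alone the medians of this list were -0.55, 0.22 and 0.44, so higher TG input values entered the differences of numbers 2 and 3. Mitochondrial ribosomal RNA took 23.1% to 34.0% of the polysome signal. A difference in mitochondrial content therefore cannot be told apart here from a shift on polyribosomes. No gene of 16962 passed, with 94 at an unadjusted p under 0.05 (limma). The smallest p-values, none passing, belonged to Baiap2l2 (-1.99 ± 0.47), Rps6kb2 (1.30 ± 0.33), Zfp964 (0.96 ± 0.28), Nfxl1 (0.92 ± 0.28) and Spink10 (-2.39 ± 0.73). All but Zfp964 were also named in input, with the opposite sign. The interaction subtracts that input difference, so their return is not a separate observation. In the replicate block fit cytosolic ribosomal proteins (median 0.11, adjusted p = 0.0197), the proteasome (0.12, 0.0197) and FMRP-bound transcripts (-0.068, 0.0169) also passed, with adjusted p from 0.928 to 0.980 with an estimated correlation in that fit, and number 1 ran against the proteasome (-0.016).

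The next comparison asked which synaptosomal transcripts are higher or lower in polysome than in input libraries in WT. The values are normalized between libraries, and the median log2 difference over the 16962 genes was 0.026. Rises and falls are therefore relative to other genes and do not give the share of a transcript on polyribosomes. Noncoding RNAs made up several of the largest falls. Bc1, a dendritic RNA that represses translation, fell from 54609 ± 27411 normalized counts in input to 1089 ± 382 in polysome (log2 difference -5.57 ± 0.46, adjusted p = 2.59e-05), and Rn7sk, the 7SK RNA that holds back transcription elongation (-4.46 ± 0.60, adjusted p = 0.00129), and Rpph1, the RNA of ribonuclease P (-4.63 ± 0.45, adjusted p = 9.57e-05), fell as well. Both of these RNAs share over 70% of their sequence with other genes. The coding genes Dennd1b (-3.80 ± 0.22), Cep112 (-3.25 ± 0.27) and Rprd1b (-3.04 ± 0.18) fell, as did the long noncoding RNA Rmst (-2.92 ± 0.22) and mt-Atp8 (-3.34 ± 0.28). Ucp2, an uncoupling protein gene of the mitochondrial inner membrane, rose from 74.4 ± 35.1 to 409 ± 128 normalized counts (2.54 ± 0.44, adjusted p = 0.00516). Tyms (1.99 ± 0.32), the histone genes Hist1h2bm (1.94 ± 0.40) and Hist1h4j (1.89 ± 0.37), Pycard (1.90 ± 0.38), Atp5e (1.89 ± 0.46), Tm4sf1 (1.84 ± 0.46) and Rnaseh2c (1.83 ± 0.53) rose too.

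Of 16962 genes, 2367 differed in WT (910 higher and 1457 lower in polysome, limma). With the replicate block 5052 differed (2358 higher and 2694 lower), and 2841, 375 and 3669 without number 1, 2 or 3. Without number 3 of WT input 648 were called, without number 3 of WT polysome 812, and without number 2 of WT input and of WT polysome 1375 and 1288. Some pairs of near-identical genes moved in opposite directions, and their single values are uncertain, as it is not stated that both fractions were quantified alike. Rps27 fell from 5184 ± 2018 to 97.9 ± 114, while Rps27rt, which shares 92.7% of its sequence with other genes, was listed at 0 in all 3 WT input libraries and at 2499 ± 229 in WT polysome. Zfp968 (2.26 ± 0.50) and Hist1h2bm share 97.3% and 58.5% of their sequence with other genes, and Rpl37rt (-2.98 ± 0.62) shares 48%.

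Nuclear genes of the respiratory chain and ATP synthase rose in 23 of 74 members and fell in 1, Ndufs1 (-1.14 ± 0.27), with a median of 0.61 (adjusted p = 1.05e-10, camera; adjusted p = 0.818 with an estimated correlation). Transcripts encoded by mitochondrial DNA fell in 9 of 13 members and rose in 0 (median -1.63, adjusted p = 1.34e-08, and adjusted p = 0.305 with an estimated correlation), and members such as mt-Co3 share sequence with nuclear copies. Transcripts bound by FMRP, an RNA-binding protein that represses translation at synapses, fell in 33 of 60 members and rose in 0 (median -0.70, adjusted p = 2.10e-13, and adjusted p = 0.618 with an estimated correlation). Dync1h1, a dynein heavy chain, fell by 1.74 ± 0.45 on the log2 scale. Autism-associated genes fell in 13 of 39 members (median -0.54, adjusted p = 1.46e-07, and adjusted p = 0.618 with an estimated correlation), with Adnp at -2.16 ± 0.29, a gene that shares 81% of its sequence. Dendritic transcripts fell in 9 of 20 members, Bc1 among them (median -0.48, adjusted p = 0.000279, and adjusted p = 0.305 with an estimated correlation).

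Presynaptic release genes fell in 8 of 40 members and rose in 2, with Unc13a at -1.55 ± 0.21 and Sncb at 1.06 ± 0.30 (median -0.30, adjusted p = 0.0168). Postsynaptic density genes fell in 6 of 40 and rose in 0, with Baiap2 at -1.14 ± 0.34 (median -0.24, adjusted p = 0.0168). Cytosolic ribosomal proteins fell in 17 of 81 (median -0.24, adjusted p = 0.000155), but their medians in the pairs were -0.55, -0.33 and 0.075 in WT and -0.47, -0.18 and 0.20 in TG, so number 3 ran the other way. Rps27, whose single value is uncertain, is a member, and the list was not retested without genes that share sequence. Nuclear long noncoding RNAs fell in 3 of 12, with Mirg at -2.27 ± 0.40 (median -0.59, adjusted p = 0.0159). Proteasome subunits rose in 6 of 31 and fell in 1, with Psmb4 at 1.11 ± 0.25 and Psmd1 at -0.66 ± 0.18 (median 0.30, adjusted p = 0.00889). Microglial markers rose in 2 of 18, Cst3 among them (0.87 ± 0.19, median 0.38, adjusted p = 0.0348). The adjusted p of these 6 lists was 0.634 to 0.846 with an estimated correlation. With the replicate block the respiratory chain list had 42 members higher and 4 lower, postsynaptic density genes 1 and 15, presynaptic genes 5 and 11, FMRP-bound transcripts 1 and 40, autism-associated genes 1 and 20, dendritic transcripts 2 and 10, the proteasome 11 and 1, microglial markers 7 and 0, nuclear long noncoding RNAs 0 and 5, and ribosomal proteins 1 and 21.

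The other 18 lists did not pass, with adjusted p from 0.222 to 0.979. They were the Shank family, mTORC1 pathway, translation factors, actin cytoskeleton, secretory chaperones, immediate early genes and blood, and the markers of direct-pathway, indirect-pathway and all medium spiny neurons, cortical excitatory neurons, striatal interneurons, midbrain dopaminergic neurons, astrocytes, oligodendrocytes, their precursors, endothelial and mural cells, and choroid and ependymal cells. Members of some of these lists passed. In the mTORC1 pathway 1 member rose, Castor1 (1.04 ± 0.29), and 6 fell. Of translation factors 4 rose and 7 fell, of secretory chaperones 4 and 1 (Sec61b 1.17 ± 0.29, Calr -1.09 ± 0.27), of actin genes 1 and 3 (Arpc4 0.60 ± 0.13, Myo5a -0.83 ± 0.16), of astrocyte markers 1 and 3 (Atp1b2 0.77 ± 0.16), and of oligodendrocyte and of endothelial and mural markers 2 and 0 (Myl9 0.80 ± 0.25). Immediate early genes and oligodendrocyte precursor markers fell in 2 members each (Egr2 -1.05 ± 0.31, Gpr17 -0.84 ± 0.16), and dopaminergic markers in 1 (Nr4a2 -0.85 ± 0.22). Cortical excitatory markers also fell in 1 member. Eif4g3 fell (-1.28 ± 0.22) and the cap-binding factor Eif4e rose (0.99 ± 0.23). The astrocyte transporter gene Slc1a3 fell (-1.08 ± 0.20) and the myelin gene Mog rose (1.01 ± 0.20). Adora2a of the indirect pathway (0.78 ± 0.36), Tac1 of the direct pathway (0.76 ± 0.32), Meis2 (-0.76 ± 0.30), Slc5a7 (-1.01 ± 0.37), Enpp2 (-0.53 ± 0.20) and Hbb-bt (0.99 ± 0.32) passed only with the replicate block (adjusted p 0.00598, 0.00912, 0.0138, 0.00637, 0.0318 and 0.0102).

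**Figure D3:**
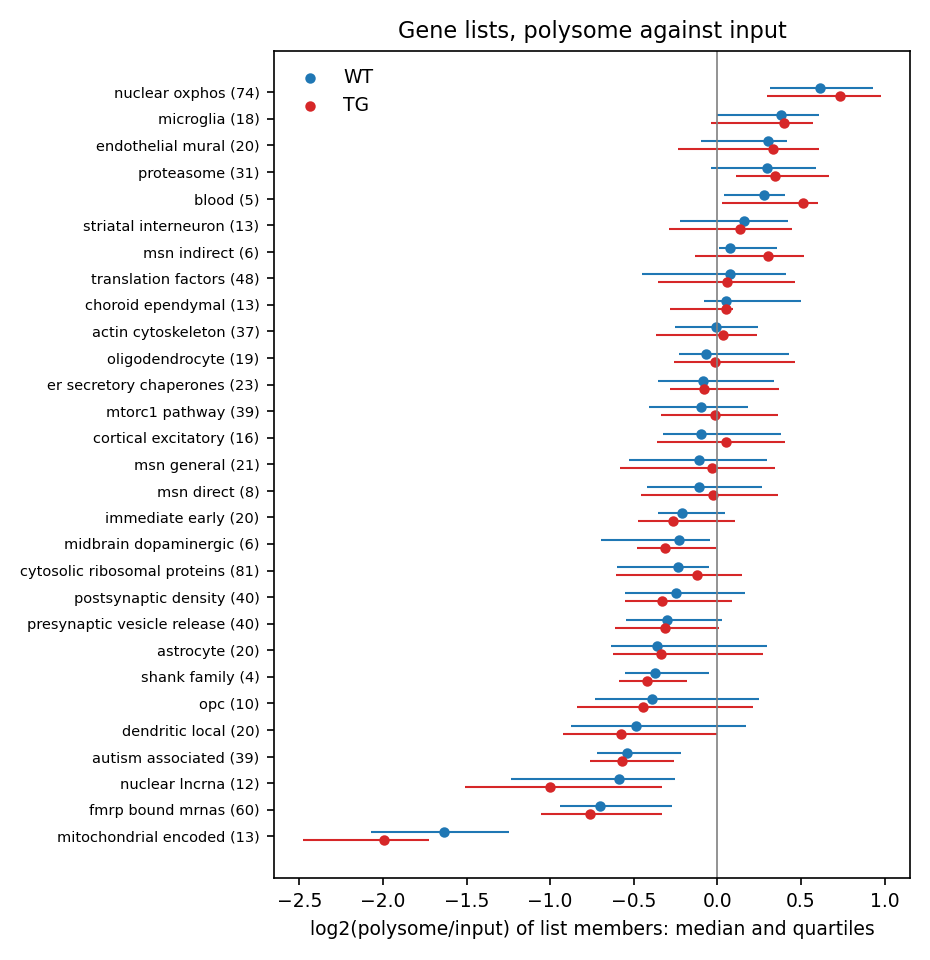
Median (points) and quartiles (lines) of log2(polysome/input) of the members of the 29 gene lists in WT and TG, with the number of measured members in brackets. Nuclear respiratory chain genes have the highest median in WT (0.61) and mitochondrially encoded transcripts the lowest (-1.63).

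The same comparison in TG gave 3062 genes of 16962 (1389 higher and 1673 lower in polysome, limma), and 5638 with the replicate block (2829 higher and 2809 lower), and 3490, 1321 and 4159 in that fit without number 1, 2 or 3. Of the genes called in WT and TG, 767 were higher in both, 1287 were lower in both, and 0 were called in opposite directions. Across the 16962 genes, which are not independent replicates, the log2 differences of WT and TG had a Spearman correlation of 0.84. FMRP-bound transcripts fell in 38 of 60 members in TG (median -0.76) and nuclear respiratory chain genes rose in 32 of 74 (median 0.74), with adjusted p = 4.6e-15 and 2.10e-10 (camera), and adjusted p = 0.412 and 0.725 with an estimated correlation. The count fell to 1205 without number 3 of TG polysome, 1340 without number 3 of TG input, 1358 without number 1 of TG polysome and 1552 without number 2 of TG input, and it was 1700 when only the 6 TG libraries were fitted.

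The difference between fractions ran with the exonic length of genes. This length covers all annotated exons of a gene, and the length of the transcripts expressed was not measured. Across 15043 protein-coding genes, the log2 difference between polysome and input had a Spearman correlation with exonic length of -0.41 in WT and -0.40 in TG, a relation across genes. The shortest eighth of genes, with a median exonic length of 1444 bases, had a median log2 difference of 0.41 in WT, and the longest eighth (median 11631 bases) had -0.38. The median exonic length was 1778.5 bases for the nuclear respiratory chain list and 13950.5 for the FMRP-bound list. With the trend on length removed in the replicate block fit, 4416 genes differed in WT and 5043 in TG, of which 3599 and 4152 were also called by the block fit.

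**Figure D4:**
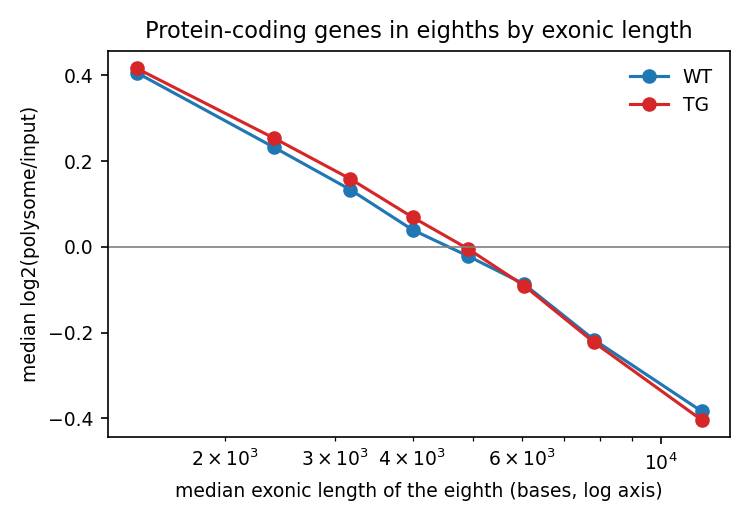
Median log2(polysome/input) of protein-coding genes in eighths by exonic length, plotted against the median length of each eighth (log axis, bases) for WT and TG. The medians run from 0.41 in the shortest to -0.38 in the longest eighth in WT, and from 0.42 to -0.40 in TG.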

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

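The list of 13 transcripts encoded by mitochondrial DNA had a median log2 difference of -0.51 between the fractions in the response to genotype, with 12 of 13 members lower and 0 passing (interaction, camera, adjusted p = 3.4e-05, and adjusted p = 1.00 with an estimated correlation). The medians of the same difference in replicate numbers 1, 2 and 3 were -0.00073, -0.39 and -1.16. In input alone the medians of TG against WT for this list were -0.55, 0.22 and 0.44. Mitochondrial ribosomal RNA took a lower share of TG than of WT polysome libraries in all 3 pairs (26.9% and 34.0%, 23.1% and 25.2%, 28.0% and 32.8%). In input its share was slightly higher in TG in numbers 1 and 3. In number 2 it was lower in TG input as well, and by more than in polysome. Between the fractions the ribosomal RNA of number 2 therefore ran against the median of the list (-0.39). Members such as mt-Co3 (99.9%) and mt-Nd4 (62.8%) share sequence with other genes. Groups of 3 libraries were not searched for outlying samples.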

How the results depend on the processing

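The tests that left out libraries by number or genes sharing sequence, removed the length trend, used a threshold of 0.1, or joined the block with an estimated correlation were chosen after the data were examined. TMM scaling, no filter, a mean of at least 50, pseudocounts of 0.5 and 5 and no variance trend kept all 5 counts within 1.5 times. The planned edgeR test on recovered reads was not run, because reads per gene could not be recovered. With the replicate block the counts were 0 in input, 1 in polysome, 0 for the interaction, 5052 in WT and 5638 in TG. It kept 2367 of the 2367 WT calls and 3061 of the 3062 TG calls, and changed the call of no other named gene or list than those given beside the results. In input the blocked adjusted p of Shank3 was 0.0631, and without number 1, 2 or 3 it was 0.0115, 0.00132 and 0.0130. At a threshold of 0.1 the block called 1, 1, 0, 6729 and 7241 genes. With the length trend removed it called 4416 and 5043, and the higher share in WT was 38.4% without the block, 46.7% with it and 51.2% with the trend removed as well. With only the TG libraries, 1700 genes were called in TG. With single libraries left out, input gave 0 to 1 genes, polysome 0 to 1, the interaction 0 to 2, WT 648 to 2566 and TG 1205 to 3263. In the replicate block without number 1, 2 or 3, input gave 1, 6 and 2 genes, polysome 3, 0 and 89, the interaction 0, 2 and 1, WT 2841, 375 and 3669, and TG 3490, 1321 and 4159. The cause of these changes was not tested. A pair of libraries per group leaves fewer degrees of freedom.

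With libraries left out, the log2 difference of Shank3 between WT fractions ran from -0.66 to 0.32, of Hbb-bs in input from -0.0061 to 0.37, and of Fosb in polysome from -0.093 to 0.78. The interaction ran from -0.59 to 0.39 for Shank3, -1.21 to 0.60 for Shank1, -0.015 to 1.38 for Slc18a2, -0.24 to 0.74 for Alas2, -0.22 to 0.011 for Pdgfra, -0.19 to 0.29 for Nos1, -0.19 to 1.09 for Upb1, -0.10 to 0.35 for C1qa, -0.60 to 0.065 for Egr2, -0.31 to 0.51 for Isl1, -0.50 to 0.033 for Syn3 and -0.063 to 0.45 for Sec61g. None of these had passed. In the replicate block the interaction was 0.088 without number 2 and 0.037 without number 3 for Shank3, -0.20 without number 2 for Alas2, -0.067 without number 3 for Nos1, and the ranges of Pdgfra and Fosb include this fit. Shank3 between WT fractions was 0.047 in the block with the length trend removed. Lists far from passing turned with the block: striatal interneurons in input (adjusted p = 0.816, and 0.938 with an estimated correlation), direct-pathway neurons (0.943, 0.988), cortical neurons, striatal interneurons and astrocytes (0.967, 0.988) in the interaction, and the actin cytoskeleton (0.984, 0.991 in WT and 0.989, 0.991 in TG) and cortical neurons (0.894, 0.945 in WT and 0.802, 0.885 in TG) between fractions. The cause was not tested.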

Other observations

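The gene families in this paragraph were picked by symbol after the data were examined, and so were the test of the replicate number, the share of genes with shared sequence and the counts of other splits. Replication-dependent histone genes, whose transcripts lack a poly(A) tail, were higher in polysome than in input in 62 of 62 members in WT and in TG, and 41 and 45 of them rose (limma), with medians of 1.19 and 1.35. The family was picked because members were seen to rise, so no list test is given for it here, and its median exonic length of 555.5 bases is short. In TG against WT polysome 60 of 61 members had higher values (median 0.22), with 0 members passing. Mitochondrial ribosomal proteins, with a median length of 2394 bases, rose in 23 of 78 members in WT and 33 in TG, and fell in 0. Pore subunits of calcium and sodium channels fell in 8 of 18 members in WT and 6 in TG, and rose in 0. Histone methyltransferases and demethylases fell in 11 of 34 members in WT and rose in 1. These families are long (median 10641.5 and 8989.5 bases), and their falls run with the trend on length. Among the other families in WT, zinc finger genes fell in 49 and rose in 7 of 365, collagens fell in 5 of 42, glutathione genes rose in 7 of 30, splicing factors rose in 5 and fell in 3 of 34, potassium channels rose in 3 and fell in 1 of 82, and GABA receptors did neither in 15.

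The replicate number marked large differences in striatal cell markers. With genotype in the fit, 3344 of 16341 genes in input and 4318 of 16312 in polysome differed between the numbers (limma, adjusted p under 0.05). All 21 medium spiny neuron markers were among them in both fractions, with a median 1.06 higher in number 2 than in the others in input and 1.07 in polysome. Cortical excitatory markers ran the other way (-0.84 and -0.65). Choroid and ependymal markers were highest in number 3 (1.68 and 1.15), as were blood genes (0.97 and 1.17). Shank3 in WT input was 2121, 4162 and 5858 normalized counts in numbers 1, 2 and 3.

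Genes that seemed nearly absent from a fraction may owe this to reads divided between near-identical genes. Of the 34 genes over 8-fold apart in WT, 70.6% shared over 50% of their 31-base sequences, against 4.76% of uncalled genes (Fisher's exact test, p = 2.2e-24). The 23 of these with measured partners had a median absolute log2 difference of 5.94 alone and 0.591 when summed with the genes they share sequence with, and 18 of the sums lay under 1. A sum follows its most abundant member, so with a far more abundant partner it returns the partner's own difference. Such sums cannot tell divided reads from a change of the rarer copy alone, and partner levels were not compared. Rps27 and Rps27rt together differed by -0.91. Sums for Rn7sk (-4.46) and for Gm10925 with mt-Atp6 (-3.09) stayed large. For these genes this argues against reads divided with their measured partners as the cause. Copies without a deposited value could not be summed, and no biological explanation was tested.

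FMRP-bound transcripts had a median of -0.70 in WT polysome against input, compared with -0.32 (95% range -0.45 to -0.18) in 10000 protein-coding lists matched on exonic length and mean level, at percentile 0, and percentile 0 was also found in TG. Nuclear respiratory chain genes lay at percentile 100 of their matched lists in both genotypes (0.61 against 0.31 in WT). A trend on exonic length as the whole cause is therefore argued against for these lists, as far as the matching reached. The lengths of the matched lists were not compared with those of the members. The draws treated members as independent, whereas the estimated correlation in WT was 0.41 for FMRP-bound transcripts and 0.54 for respiratory chain genes. The percentiles are therefore not p-values. The unstated normalization and a difference in ribosome loading stay open and untested. Presynaptic release genes (percentile 1.54 in WT and 1.12 in TG), dendritic transcripts (1.32 and 0.75) and cytosolic ribosomal proteins (0 and 0, with number 3 running the other way) also lay outside the central 95% of theirs. The ribosomal list includes genes that share sequence, such as Rps27. Postsynaptic density genes (31.2 and 8.14), the proteasome (81.9 and 86.6) and autism-associated genes (3.98 and 3.68) lay within it, so length could account for their medians.

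A hypothesis of this work is that circular RNAs, which a total RNA library keeps and which rarely carry ribosomes, add reads to their host genes in input, an idea that arose after genes such as Rmst were seen to fall. A list of 21 brain host genes, drawn from general knowledge before their values were seen and without the genes already seen to fall, had a median of -0.71 in WT and -0.73 in TG. Lists matched on exonic length and mean level had -0.30 and -0.33, which placed the hosts at percentiles 0.27 and 0.21. These draws too treated members as independent. Of the 21 genes 9 fell in WT and 11 in TG, with Tulp4 at -1.43 ± 0.17 and Unc79 at -1.48 ± 0.26, and Rtn4 rose (0.56 ± 0.15). This is consistent with the hypothesis, but the values are totals per gene, circular and linear RNA were not separated, and unspliced nuclear RNA in input was not tested.

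Other splits of the same libraries were counted for each number of called genes. Splits of 6 libraries into 3 and 3 are 10, too few for a share under 0.05. For genotype in input the real count was 0 and the highest of the others 10 (10 of 10 splits gave as many), and in polysome 0 and 4 (10 of 10). Splits with calls in input parted 1 pair of same-numbered libraries, and the 3 others that parted all 3 pairs, like the real one, gave at most 0. For polysome against input the real counts were 2367 in WT and 3062 in TG, the highest other was 0 in each, and 1 of 10 splits, the real one, gave as many. The other splits mix the fractions and leave their large difference in the spread. A count of 0 was therefore largely set in advance there and decides nothing about chance either. For the interaction the real count was 0, and 100 of 100 drawn splits gave as many. Every split reaches a real count of 0, so for genotype and the interaction these shares decide nothing about chance. The highest gave 2266 genes, the next 23. It set number 3 against number 2 in opposite directions in the 2 fractions, which points to the replicate numbers as a structure of the samples.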
